A study of Mus musculus with 8 samples.

How the data were processed

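RNA was sequenced from 8 mouse skin wound samples, 4 treated with vehicle and 4 with a PTEN inhibitor, collected on day 3 after wounding. Per the labels' protocols, ribosomal RNA was depleted from total RNA and strand-specific libraries were made by dUTP incorporation after random priming. The submitters' processing notes name STAR 2.7.8a, Partek and DESeq2, without giving the roles of these tools. They give the genome build as mm39 and as GRCm39, which are names of the same mouse assembly. How reads were counted per gene and how the values were normalized is not given in the sources used here. The deposited table is described by its name as normalized counts.

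Samples were put into groups by their titles, which also gave replicate numbers. The tests were fixed before the data were examined: limma on log2(normalized value + a pseudocount) for each gene, and limma's camera for 36 gene lists. Beside camera, limma's fry and an estimated inter-gene correlation were planned for the gene lists. None of these tests was run. Each of the table's 8 value columns is headed by a code that matches no sample label, so placing a column in a treatment group would have required its position or its values, and neither is evidence of treatment. The number of per-sample columns left unused is 8, and 0 were used.

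The table's header and its gene identifiers were read with Python 3.11.15. Identifiers were matched without their version to a table of mouse gene symbols, and 27574 of the 28734 identifiers had a symbol, leaving 1160 without one. For each gene list fixed before the data were examined, the members with a row were counted by symbol. Symbols that the name table lacks were also looked up through the synonyms of a RefSeq gene table (GRCm38.p6), as an alternative chosen after seeing the data. The gene annotation at hand is for GRCm38, whereas the notes name GRCm39, so no coordinates are given. The rule for named genes called for Pten, a fixed panel of vessel, immune and skin genes, and genes ranked by test results. It was not applied because no test was run and no column was assigned to a treatment.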

Results

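The transcriptome of healing mouse skin was measured by RNA sequencing to compare wounds given a PTEN inhibitor with wounds given vehicle. PTEN is the lipid phosphatase that opposes PI3K and thereby limits AKT signalling, and the study's title links it to immune response, angiogenesis and lymphangiogenesis in venous leg ulcers that do not heal. Wounds of 5 mm were made on the backs of C57 mice aged 8 weeks, held open by a 10 mm silicone splint, treated, and collected on day 3. The labels describe 8 skin samples, of which 4 received vehicle and 4 received the inhibitor. The labels do not name the inhibitor or its dose.

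The values were deposited as a single table with 28734 genes in rows, each named by an Ensembl mouse gene identifier, and 8 columns of values. The labels name the samples as numbered controls and numbered PTEN inhibitor samples, 4 of each, whereas the columns are headed by a letter, R or L, followed by a number. Of the 8 headings, 0 matched a sample's title or description, and 0 occurred anywhere else in the labels. No column was therefore assigned to a treatment. The number of group comparisons made was 0, and no expression level, fold change or test is reported for any gene. Column order and the level of any gene were not used to assign treatments. The depth of each library is unknown here. No value was used, and values described as normalized counts need not show depth.

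The gene identifiers that had a symbol show genes that the table lists, independently of treatment. The PTEN, PI3K and AKT pathway list had a row for 25 of its 25 members, including Pten itself, and the list of FOXO target genes, which AKT signalling represses, had a row for 25 of 25. Among vessel genes, the blood endothelium list had rows for 28 of 28 members, the list of sprouting and angiogenic factors for 26 of 26, and the lymphatic list for 25 of 25. The immune lists were as fully represented, with 25 of 25 neutrophil genes, 25 of 25 monocyte and macrophage genes, 20 of 20 genes of alternatively activated macrophages, and 31 of 31 T and NK cell genes. The cytokine and chemokine list had 29 of 31, and the other two, Il36a and Il36g, matched a row through RefSeq synonyms. The basal keratinocyte list had rows for 20 of 20 members, the wound-edge activated keratinocyte list for 26 of 27, without Defb14, and the differentiated epidermis list for 30 of 31. The last of these lacked only the symbol Loricrin, a newer name for the listed gene Lor, so it was complete by gene, and the counts over all lists treat the 2 symbols as separate memberships. Outside the epidermis, the fibroblast and extracellular matrix list for 27 of 27, and the skeletal muscle list for 30 of 30. A row shows that a gene was listed, not that it was expressed at any given level. The share of all symbols in the gene name table that had a row was not computed. The counts of list members therefore do not set any list apart from other genes.

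Over all 36 gene lists, 785 of 811 memberships had a row by gene symbol, and 27 lists had a row for every symbol on them. The hair follicle list was the least complete of the tissue lists, with 21 of 30. Its members with no matching row were the keratins Krt72, Krt31, Krt33a, Krt34, Krt81 and Krt85 and the 3 keratin-associated (Krtap) genes on the list. Krt85 was missing from the gene name table, and RefSeq synonyms gave no row for it either. The red blood cell list had rows for 11 of 12 members, without Ahsp, and the list of ribosomal and abundant non-coding RNA for 9 of 15. Ahsp and, in the second of these lists, Rn18s, Rn45s and Rn28s1 were, like Krt85, absent from the gene name table. Matching by symbol could not find these genes whatever the deposited table lists. The other members of the second list without a row, Rn7sk, Rn7s1 and Rn7s2, are in the gene name table. The glycolysis and hypoxia list, with 22 of 23, and the adipocyte list, with 22 of 23, were complete once RefSeq synonyms were added. The sex-linked list had rows for 2 of 6 members, Xist and Tsix, and none matched the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y. For members that the name table does hold, such as the Y-linked genes, the reason for a missing row was not examined. This includes whether a filter on low values was applied. It also includes whether such a gene is among the 1160 identifiers without a symbol, which matching by symbol could not find.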

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

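No alternative analysis of expression values was run, because 0 of the 8 value columns were assigned to a sample. This covers other pseudocounts, filters, scalings, variance models, library weights, left-out libraries, composition and sex covariates, thresholds, gene list tests and count models. No paired analysis was possible because the columns carry no replicate number from the labels. Even with those numbers the pairing would be unknown, because the sample titles do not say that equal numbers mark paired animals. The one alternative that was run, chosen after seeing the data, added RefSeq synonyms when gene symbols were matched. It raised the list memberships with a row from 785 to 789 of 811 and the lists with a row for every symbol from 27 to 30 of 36. The hair follicle list stayed at 21 of 30. Only symbols that the gene name table lacks could gain a row this way. In the hair follicle list that was Krt85 alone, so the unchanged count does not test the other members without a row. The column headings carry 6 different numbers, of which 2 head both an R and an L column. The labels do not say what these codes mean, and whether columns sharing a number come from the same animal was not tested.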
